A study of Penaeus vannamei with 6 samples.

How the data were processed

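The series profiled RNA of the stomach and the hepatopancreas of the Pacific white shrimp, Penaeus (Litopenaeus) vannamei, in relation to acute hepatopancreatic necrosis disease, a bacterial disease of farmed shrimp in which toxin-carrying strains of Vibrio parahaemolyticus damage the hepatopancreas. Per the labels, 3 pools of shrimp were used: a control pool of 3 normal shrimp sampled at 0 h, an infected pool of 3 shrimp sampled 24 h after challenge with the disease-causing Vibrio strain, and a survivor pool of 4 shrimp described as resistant, which had outlived feeding with a preparation of that strain that the labels call FKC. The labels do not spell out FKC, and a sampling time of the survivors is not given in the sources used here. Per the labels' protocols, the RNA of a tissue was combined within a pool before a stranded mRNA library was made for Illumina MiSeq sequencing, so each tissue and pool has 1 library, 6 in all, and no replicate library stands behind a comparison of pools.

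The authors deposited estimated counts per assembled gene for the 6 libraries, and a second matrix of scaled abundances of the same genes. Bowtie, RSEM and edgeR are named in the submitters' processing notes, without versions. Read filters, assembly settings and the strand setting of the counting are not given in the sources used here. The identifiers have the form that the Trinity assembler gives to genes put together from the reads themselves, per the file's own rows, and they number 79591. The column sums of the second deposited matrix, relative to the fixed sum of a TPM column, have a geometric mean of 1. That is what TPM values divided by a trimmed-mean-of-M-values (TMM) factor per library give, a reading that comes from the values. Between 2.98% and 5.07% of the estimated counts of a library were not whole numbers, and all were rounded to whole reads here before use.

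Of the 79591 identifiers, 0 matched a name in the RefSeq gene table of the species, so the files do not pair the assembled genes with gene names. The gene lists fixed for antimicrobial peptides, digestive enzymes, cuticle proteins and other groups could therefore not be used, and the biology is described through groups of genes defined by tissue and by response. An assembler can split 1 gene into several features where animals carry different alleles or where near-identical copies exist, and reads can move between such features. Features that share an identifier up to its last part belong to 1 assembly cluster, and there were 60966 clusters. For each feature named in a comparison of pools, the sum over its cluster is given where it did not pass the same rule.

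Library sizes were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, computed from all 6 libraries, and levels are given as CPM, counts relative to these scaled library sizes. For each pair of pools within a tissue, a feature was tested when it had at least 20 reads in 1 of the 2 libraries. It was called higher or lower when the scaled ratio was at least 4-fold and the bound nearest 1 of its 95% exact conditional-binomial (Clopper-Pearson) interval lay beyond 2-fold. A library with 0 reads entered the ratio with 0.5 read. Folds against 0 reads are printed as at least the fold against a floor of 3 reads in that library. This floor leaves out counting error in the other library. The bound of the 95% interval lies lower for each named gene, as 593.8 against 730.9 for TRINITY_DN13601_c0_g1 in the infected stomach. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules, and they say nothing of the spread between shrimp. No p-value was computed for a comparison of pools. Named features are, per comparison, the 2 higher and the 2 lower whose interval bound nearest 1 was most extreme, as fixed beforehand for files without gene names.

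A hepatopancreas-enriched feature had at least 50 reads in the hepatopancreas library of a pool and a scaled level at least 16 times that of the stomach of the same pool. Stomach-enriched features were defined the other way round. For a comparison of 2 pools the set was taken from the third pool, so that no library of the comparison defined it. The median log2 ratio of a set was placed among the medians of 10000 random lists of the same size matched on mean abundance in 20 bins, as a description of these libraries. Intervals of such medians come from 1000 resamplings of the features. Shares of reads carry Wilson 95% intervals.

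The difference between tissues is the comparison with replicates, because each tissue was sampled from 3 pools. It was tested with edgeR's quasi-likelihood test, two-sided, with pool as a block, edgeR's expression filter and Benjamini-Hochberg adjustment at 0.05. The replicates differ in treatment. With pool as a block, these p-values measure how the tissue difference varies across the 3 differently treated pools. Standard errors are the size of the log2 fold change over the square root of its F statistic, an approximation. DESeq2 1.42.0 and limma 3.58.1 served as alternatives. All other values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

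The procedures were tested on simulated data with 200 changed features. With counting error alone, at most 1 unchanged feature was called in any of the 6 comparisons of pools, between 94.0% and 100% of features raised 8-fold were called, and the intervals covered the true ratio in 95.5% to 96.3% of features. A spread between pools was then added, a biological coefficient of variation of 0.4 chosen after seeing the data. The tissue test estimated 0.455, but with pool as a block, so that value does not measure the spread between pools within a tissue. With the added spread, the size rule called 218 to 327 unchanged features per comparison, and the intervals covered the true ratio in 46.3% to 53.8% of features. As few as 83.0% of features raised 8-fold and 78.3% of those lowered 8-fold were called. In a simulation of the tissue test over 9512 features, 100% of 16-fold and 43.0% of 4-fold changes were recovered, with 4 calls among unchanged features.

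Comparisons that share the control library were set against 100 simulations of unchanged pools compared with that library, and against the overlap of independent lists. Alternatives were scaling by library totals or by DESeq2 size factors, no minimum read number, libraries thinned to the smallest total of 1215614 reads, the authors' scaled matrix as log2(value + 1), other read minimums, fold rules and enrichment folds, and, chosen after seeing the data, counts summed over assembly clusters and, for shared responses, a minimum of 20 reads in the control library. All other alternatives, the size rule and the sets' definitions were fixed before the data were examined.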

Results

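The 6 libraries held between 1215718 reads, in the survivor stomach, and 2492704 reads, in the infected stomach. The other totals were 2358482 reads for the control stomach, 1695050 for the control hepatopancreas, 1381456 for the infected hepatopancreas and 1278616 for the survivor hepatopancreas. A count of 0 in a library allowed a level of up to 1.09 CPM in the infected stomach, the lowest such limit, and 2.73 in the infected hepatopancreas, the highest. At least 1 read was found for 42180 assembled genes in the infected stomach and for 23793 in the infected hepatopancreas, and 12977 genes reached 20 reads in at least 1 library. The 10 most abundant genes took between 16.7% and 26.2% of a library's reads.

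The tissue of origin was the main divide among the libraries. Across 2654 genes, Spearman's rho between stomach libraries of different pools lay between 0.838 and 0.880, and the control and infected hepatopancreas reached 0.879, while the survivor hepatopancreas stood at 0.789 to the control and 0.790 to the infected hepatopancreas. Between stomach and hepatopancreas of the same pool, rho was 0.627 in the control, 0.589 in the infected and 0.763 in the survivor pool. Genes are not independent replicates, and these values describe the libraries.

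The hepatopancreas, the digestive gland of shrimp, and the stomach were first compared with each other over the 3 pools. Of 9512 genes tested, 1346 were higher in the hepatopancreas and 1579 were higher in the stomach at an adjusted p below 0.05 in edgeR's quasi-likelihood test. In 3 of 3 pools, 1343 and 1578 of these differed in the called direction. The test itself selects genes that differ alike over the pools, so this agreement is no separate support. TRINITY_DN14901_c0_g1 averaged 759.1 ± 790.0 CPM in the hepatopancreas (SD, n = 3) and 0.121 ± 0.21 in the stomach (SD, n = 3), with a log2 fold change of 12.16 ± 0.72 (SE) and an adjusted p of 0.0132 in edgeR. TRINITY_DN11616_c0_g1 averaged 756.6 ± 577.4 in the hepatopancreas against 0.135 ± 0.234 in the stomach (SD, n = 3 each), a log2 fold change of 11.98 ± 1.02 (SE) with the same adjusted p. On the stomach side, TRINITY_DN24277_c11_g19 averaged 1179 ± 177.9 CPM against 0.499 ± 0.461 in the hepatopancreas, and TRINITY_DN24139_c8_g1 averaged 501.6 ± 302.2 against 0.248 ± 0.43 (SD, n = 3 each). Their log2 fold changes, hepatopancreas over stomach, were -10.99 ± 0.91 and -10.69 ± 0.78 (SE), with an adjusted p of 0.0132 in edgeR for both, and they belong to clusters of 32 and 23 features among which reads can be shared. The control hepatopancreas held 475.9 CPM of TRINITY_DN14901_c0_g1, the infected 1652 and the survivor 149.7. Without the control or the infected pool edgeR called 0 genes, with 2798 and 3008 at an unadjusted p below 0.05, where DESeq2 called 1360 and 1263 and limma 1071 and 1421; without the survivor pool edgeR called 2743 and 2739. The 4 named genes kept log2 fold changes of 12.00, 13.79, -10.34 and -12.21 in edgeR without the control pool (adjusted p = 0.0793) and of 12.30, 10.75, -11.70 and -10.58 without the infected pool (adjusted p = 0.0650). Their adjusted p lay between 4.44e-34 and 0.0793, both in edgeR, over the alternatives run on single features. Sums over clusters gave no value for these genes.

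Infection was examined first in the stomach. There, 1452 of 10471 tested genes were higher and 371 were lower in the infected than in the control library. The control pool was sampled at 0 h and the infected pool at 24 h, without an unchallenged pool at 24 h. Time and handling therefore cannot be told apart from infection, here or in the hepatopancreas. The lower genes numbered 567 where no minimum read number was set, 241 at equal depth and 234 where counts were summed over clusters. No read was seen in the control stomach for 680 of the higher genes. Which organism an assembled gene came from was not tested, so the higher genes cannot all be taken as shrimp genes. TRINITY_DN3154_c0_g1 stood at 7442 CPM in the infected stomach and 2.84 in the control stomach, a ratio of 2620 (95% counting interval 1271 to 6517), and at 187.0 in the survivor stomach. TRINITY_DN26672_c0_g2 stood at 3514 in the infected stomach against 0.812 in the control stomach, a ratio of 4330 (1198 to 35758), and at 86.0 in the survivors. Neither of these exceeded 2.73 CPM in any hepatopancreas library. Genes enriched in the stomach of the survivors had a median log2 ratio of 0.0035 (-0.29 to 0.30 over resampled genes), with 129 of 422 higher and 37 lower, and the sign of the median depended on the enrichment and read minimum chosen.

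Among the lower genes, TRINITY_DN13601_c0_g1 fell from 797.8 CPM in the control stomach to 0 reads in the infected stomach, at least 730.9-fold lower, and TRINITY_DN4964_c0_g2 fell from 395.7 to 0 reads, at least 362.5-fold lower. Both belong to assembly clusters whose summed level did not pass the size rule, with summed log2 ratios of 0.34 and -0.41. The higher genes came from 1085 assembly clusters, with 35 of them in a single cluster of 119 features, and 716 were the only feature of their cluster. Of the 736 higher genes in clusters of several features, 619 had a cluster sum that was also called higher, and of the 223 such lower genes, 103 had a cluster sum that was called lower. The comparison has no replicate check, and a simulated spread between pools of 0.4 gave 327 calls among unchanged features.

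In the hepatopancreas of the same shrimp, 239 of 6111 tested genes were higher and 174 were lower after infection, with 362 higher where no minimum read number was set and 134 where counts were summed over clusters. TRINITY_DN20943_c0_g1 rose from 2.23 to 464.1 CPM, a ratio of 208 (95% counting interval 70.7 to 1011), and stood at 12.3 in the survivors. TRINITY_DN2553_c0_g2 had 0 reads in the control hepatopancreas and 178.4 CPM in the infected one, at least 79.8-fold higher, and its cluster of 2 features rose from 175.8 to 875.4, which is 4.98-fold. The 2 leading lower genes were again TRINITY_DN13601_c0_g1, at least 290.5-fold lower, and TRINITY_DN4964_c0_g2, at least 282.4-fold lower, with cluster sums that passed no rule at log2 ratios of 0.40 and -0.69. Of the genes in clusters of several features, 65 of 151 higher and 33 of 90 lower ones had a cluster sum called alike. Genes enriched in the hepatopancreas of the survivors had a median log2 ratio of 0.29 (0.09 to 0.49 over resampled genes) between infected and control hepatopancreas, with 30 of 285 higher and 13 lower, a median above those of all 10000 random lists. A simulated spread between pools of 0.4 gave 232 calls among unchanged features, against the 413 observed, and with no replicate library the difference between those numbers cannot be tested.

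**Figure D1:**
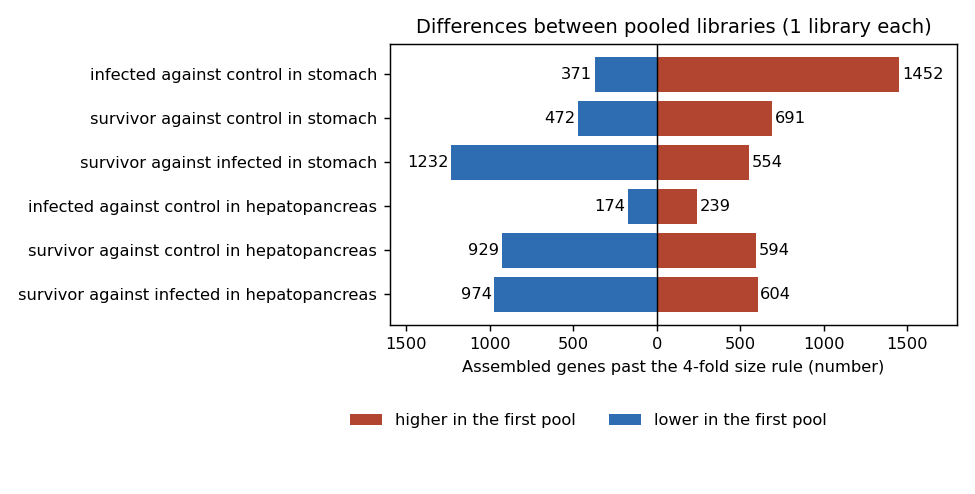
Number of assembled genes past the 4-fold size rule in each comparison of 2 pooled libraries, with genes higher in the first-named pool to the right and genes lower in it to the left; the horizontal axis is a number of genes and there are no error bars, as each pool has 1 library per tissue. The infected stomach had 1452 higher genes against the control and the survivor stomach had 1232 lower genes against the infected; scaled by library totals, the 2 survivor comparisons in the hepatopancreas turn to more higher than lower genes, 1077 against 635 and 1185 against 678.

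The differences between the infected and the control pool overlapped between the 2 tissues, with time and handling not told apart from infection. Among 4327 genes tested in both, 24 were higher in both tissues, where independent lists would share 1.33, and 32 were lower in both, where they would share 1.74. The log2 ratios of the tissues correlated across genes at a Spearman's rho of 0.35 (0.33 to 0.38 over resampled genes). Of the 1452 genes higher in the infected stomach, 86 were measured in the infected and control hepatopancreas, and 24 of those were higher there and 2 lower. The stomach and hepatopancreas libraries of a pool came from the same shrimp, so the overlap includes what these animals carried. Over the 3953 genes with 20 or more reads in the control library of both tissues, 4 were higher in both, against 0.081 for independent lists, and 32 were lower in both, against 1.79.

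Survivors were compared with controls next. They differ from the controls in exposure to FKC and in selection by survival, and their sampling time is not given. The comparison therefore does not isolate resistance to the disease. In the stomach, 691 of 8724 tested genes were higher and 472 were lower in the survivors, with 1386 higher where no minimum read number was set and 299 lower where counts were summed over clusters. TRINITY_DN13839_c1_g1 stood at 3520 CPM in the survivor stomach against 1.62 in the control stomach, a ratio of 2168 (95% counting interval 846.3 to 7961), while its cluster of 3 features held 5119 in the survivors and 6237 in the controls. TRINITY_DN13796_c0_g3 was at least 345.2-fold higher, at 420.2 against 0 reads, with a cluster that held 674.1 and 868.4. On the lower side were TRINITY_DN13601_c0_g1, at least 334.1-fold lower, with a cluster log2 ratio of -0.02, and TRINITY_DN6798_c0_g5, at least 117.9-fold lower, with a cluster that held 178.3 in the survivors and 437.0 in the controls. None of the 4 clusters passed the size rule, and of the genes in clusters of several features, 268 of 387 higher and 126 of 283 lower ones had a cluster sum called alike.

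In the survivor hepatopancreas, 929 of 7423 tested genes were lower and 594 were higher than in the control. Genes enriched in the hepatopancreas, as defined in the infected pool, made up much of the lower side: 415 of 887 were lower and 15 were higher, and lower genes made up 46.8% of the set and 7.86% of all other genes, which were not matched on abundance. Their median log2 ratio was -1.85 (-2.02 to -1.72 over resampled genes), below the medians of all 10000 random lists, the lowest of which was -0.47. Genes enriched in the stomach had a median log2 ratio of -0.44 (-0.56 to -0.33) in the survivor stomach against the control stomach, with 192 of 1030 higher and 135 lower. Of the 1566 genes in this set, 1030 were tested. A gene low in the control was tested only where the survivors were high, which raises the share of higher genes. Higher genes made up 18.6% of the tested genes of this set and 6.49% of all other genes. Lower genes made up 13.1% and 4.38%, without matching on abundance and without a test of the difference. The median also lay below those of all 10000 random lists, the lowest of which was -0.22, and it was -0.12 with 64-fold enrichment.

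TRINITY_DN13796_c0_g3 and TRINITY_DN21765_c0_g5 led the higher genes of the survivor hepatopancreas, at least 162.3-fold and 88.8-fold higher than the control's 0 reads, and TRINITY_DN13601_c0_g1 and TRINITY_DN11501_c1_g1 led the lower ones, at least 450.5-fold and 311.7-fold lower. None of the 4 had a cluster sum past the size rule, with log2 ratios of the sums of -0.83, -0.68, -0.04 and -1.51 in that order. Of the genes in clusters of several features, 138 of 300 higher and 370 of 491 lower ones had a cluster sum called alike. Scaled by library totals, which moves the median log2 ratio of all genes from -0.05 to 0.70, the split turned to 1077 higher and 635 lower genes, and the hepatopancreas-enriched genes kept a negative median of -1.15. The comparison has no replicate check.

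**Figure D2:**
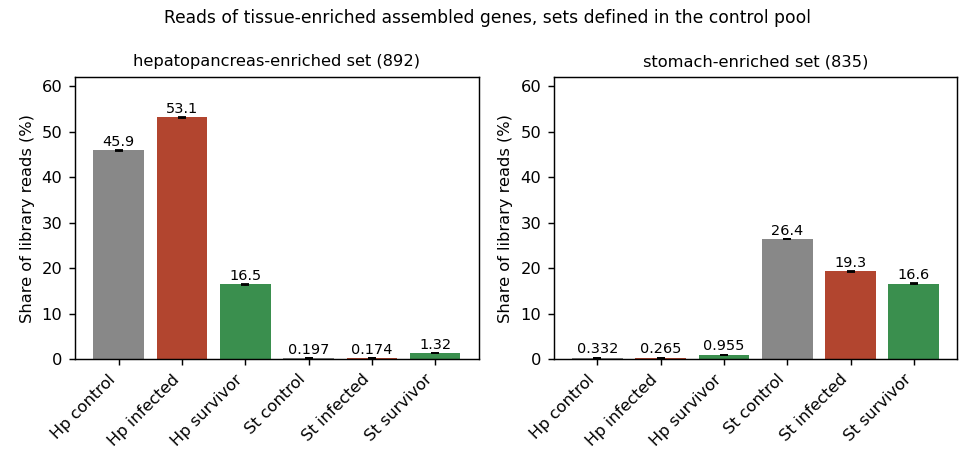
Share of each library's reads, in percent, taken by genes enriched in the hepatopancreas (Hp, left) and in the stomach (St, right), with both sets defined in the control pool; bars are single pooled libraries and the error bars are Wilson 95% intervals, which cover counting error only. Hepatopancreas-enriched genes took 45.9%, 53.1% and 16.5% of the reads of the control, infected and survivor hepatopancreas, and 1.32% of those of the survivor stomach. Defining the sets in the control pool by itself raises their share in the control library of their own tissue.

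Shares of reads gave the same comparison without a ratio per gene. The 892 genes enriched in the control hepatopancreas took 45.9% of the reads of that library (Wilson 95% interval 45.8% to 46.0%), 53.1% in the infected hepatopancreas (53.1% to 53.2%) and 16.5% in the survivor hepatopancreas (16.4% to 16.5%). In the stomach the same genes took 0.197% of the control's reads, 0.174% of the infected and 1.32% of the survivors' (1.30% to 1.34%). The 835 genes enriched in the control stomach took 26.4% of the reads in the control stomach, 19.3% in the infected and 16.6% in the survivor stomach, and 0.332%, 0.265% and 0.955% in the 3 hepatopancreas libraries in the same order. Both sets were chosen in the control pool. This by itself raises their share in the control library of their own tissue and lowers it in that of the other tissue. With sets defined in the infected pool, the 927 hepatopancreas-enriched genes took 46.4% of the reads in the control and 17.4% in the survivor hepatopancreas, and 0.376% in the control, 0.195% in the infected and 1.57% in the survivor stomach. Between control and infected stomach the direction depended on the set: stomach-enriched genes defined in the infected pool took 25.5% and 29.1%, and those defined in the survivors, a pool outside that comparison, took 22.7% and 20.2%. In the survivor stomach the infected-defined genes took 16.5%.

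Survivors were also set against infected shrimp. In the stomach, 1232 of 10007 tested genes were lower and 554 were higher in the survivors, and in the hepatopancreas 974 of 7172 were lower and 604 were higher. The hepatopancreas-enriched genes defined in the control pool had a median log2 ratio of -2.16 (-2.28 to -2.04 over resampled genes) in the hepatopancreas, with 466 of 859 lower and 10 higher, below the medians of all 10000 random lists. TRINITY_DN12136_c0_g1 stood at 2515 CPM in the infected hepatopancreas, 191.4 in the control and 1.17 in the survivors, a survivor-to-infected log2 ratio of -11.07, and TRINITY_DN11501_c1_g1 was at least 513.7-fold lower in the survivors, with a cluster 3.62-fold lower. TRINITY_DN22313_c1_g3 and TRINITY_DN23585_c0_g1 were at least 150.7-fold and 142.7-fold higher in the survivor hepatopancreas than in the infected, and their clusters stood at 451.9 and 390.9 CPM in the survivors against 2.23 and 10.4 in the control hepatopancreas.

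In the stomach, TRINITY_DN13839_c1_g1 was higher in the survivors than in the infected shrimp by a ratio of 1935 (95% counting interval 828.4 to 5961) and TRINITY_DN4964_c0_g2 was at least 333.2-fold higher, with cluster log2 ratios of 0.09 and 0.51. TRINITY_DN17167_c3_g42 was at least 326.9-fold lower in the survivors; its cluster of 119 features held 0.812 CPM in the control stomach, 4848 in the infected and 1605 in the survivors, and at most 1.82 in each hepatopancreas library. TRINITY_DN13601_c0_g2 was at least 298.4-fold lower, with a cluster log2 ratio of -0.36. The stomach-enriched genes had a median log2 ratio of -0.70 (-0.80 to -0.58), with 132 of 779 lower and 31 higher, also below the medians of all 10000 random lists. A cluster sum called alike stood behind 178 of 313 higher and 404 of 642 lower genes in clusters of several features in the stomach, and behind 158 of 301 and 430 of 530 in the hepatopancreas. Scaled by library totals, the hepatopancreas comparison turned to 1185 higher and 678 lower genes, with the median of all genes moving from 0.13 to 0.88, and without a minimum read number the stomach comparison turned to 1371 higher and 1281 lower.

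**Figure D3:**
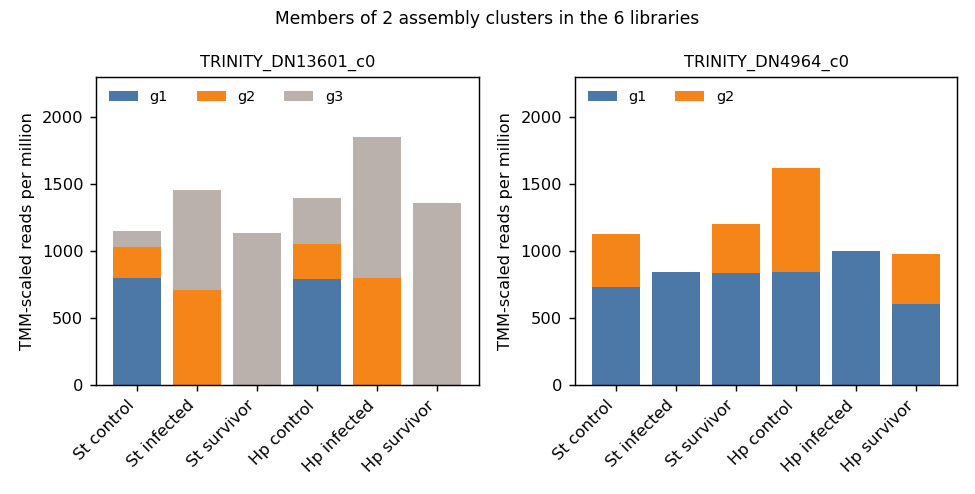
CPM of the members of 2 assembly clusters in the stomach (St) and hepatopancreas (Hp) libraries, stacked so that the bar height is the cluster's sum; each bar is 1 pooled library, without error bars. The first member of the left cluster was at 797.8 and 793.2 in the control libraries and at 0 in the other 4, while the cluster's sum lay between 1135 and 1855.

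The genes higher in the infected than in the control library were followed into the survivors. Of the 1452 genes higher in the infected stomach, 886 were lower and 8 were higher in the survivor than in the infected stomach, with a median log2 ratio of -3.16, or -2.37 with genes at 0 reads placed at their floor. These genes were chosen for a high value in the infected library, which by itself moves such a median below 0. Against the control, 247 of the 1452 were higher and 2 lower in the survivor stomach, while 1082 had under 20 reads in both of those libraries. Most of the genes were low in the control and entered this comparison only where the survivors were high; of the 164 with 20 or more reads in the control, 47 were higher in the survivors, 2 were lower and 115 passed no rule. Of the 239 genes higher in the infected hepatopancreas, 173 were lower in the survivors than in the infected, and against the control 43 were higher and 20 lower, with 120 under 20 reads in both libraries. Of the 69 with 20 or more reads in the control hepatopancreas, 6 were higher and 20 lower in the survivors.

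In the stomach, the ratios of the infected and the survivor pool to the shared control library correlated across 8351 genes at r = 0.65 with a covariance of 1.78, where unchanged pools simulated with counting error gave r = 0.42 and a covariance of 0.05, and with a spread of 0.4 gave 0.48 and 0.43. Both pools were higher than the control for 247 genes, against 16.1 for independent lists and 28.5 in the simulation with spread, and lower for 142, against 21.0 and 10.7. In the hepatopancreas r was 0.35 across 5843 genes with a covariance of 0.77, where the simulations gave r = 0.54 in both cases and covariances of 0.06 and 0.50. There, 43 genes were higher in both pools, against 2.12 for independent lists and 25.5 in the simulation with spread, and 112 were lower in both, against 27.7 and 9.03. The control is a single library and cannot be split, so part of the excess may come from it. A gene low in the control is tested in both comparisons only where both pools are high, which raises the number higher in both. A gene at 0 reads in the control stayed at 0 in the simulations, which thus could not call it higher in both. Over genes with 20 or more reads in the control, 47 were higher in both pools in the stomach, with r = 0.44 and a covariance of 0.72, and the simulation with spread gave 10.7 genes, r = 0.44 and 0.37. In the hepatopancreas 6 were higher in both, with r = 0.26 and a covariance of 0.50, and the simulation gave 6.74 genes, r = 0.46 and 0.37.

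Between the tissues of the survivors, 101 of 5216 genes were higher than the control in both stomach and hepatopancreas, where independent lists would share 22.6, and 38 were lower in both, where they would share 2.48. Spearman's rho between the log2 ratios of the tissues was 0.39 (0.36 to 0.41 over resampled genes). Over the 3953 genes with 20 or more reads in both controls, 7 were higher in both tissues, against 0.655, and 38 lower, against 2.82. Genes that were higher in the survivors than in both other pools numbered 397 in the stomach and 400 in the hepatopancreas, with 59 in common against 11.8 for independent lists among 4844 genes, and 3 in common against 0.323 among the 3638 of these with 20 or more reads in both controls. Genes lower than in both other pools numbered 152 in the stomach and 575 in the hepatopancreas, with 6 in common against 0.204.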

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

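The tests of the hepatopancreas-enriched genes, of sister features and of the tissue split were chosen after the result was seen; those of clusters called in both directions and of transcripts carried by a pool were written before their results.

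Between stomach and hepatopancreas, 2 genes were called in opposite directions after infection, where independent lists would give 3.05, and 20 genes were called in opposite directions in the survivors, where they would give 17.9. They were flagged gene by gene for their opposite calls. The numbers are close to those of independent lists, and more genes were called alike, 56 and 139. Over the 3953 genes with 20 or more reads in both controls, 0 and 3 were called in opposite directions and 36 and 45 alike. With 1 library per tissue and pool, the difference between the tissues was not tested.

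The lower level of hepatopancreas-enriched genes in the survivor hepatopancreas was weighed against 3 technical explanations. Stomach tissue in that sample would bring stomach-enriched reads, and these imply a stomach share of 3.67% of reads where the hepatopancreas-enriched genes, as defined in the infected pool, lost 62.6% of theirs. A few very abundant genes are not the whole cause, since without the 10 most abundant members the share still fell 2.24 times, from 27.9% to 12.4%, against 2.67 times with them. Scaling moves its size, with a median log2 ratio of -1.15 (-1.31 to -0.99) by library totals against -1.85, and leaves it below 0. A tissue that was not profiled in the dissected sample, a difference in the survivors' feeding, age or moult, and a lasting change after exposure stay open and untested, as 1 pooled library cannot separate them.

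The rise of hepatopancreas-enriched reads in the survivor stomach, to 1.32%, was set against carry-over of the survivors' own hepatopancreas. A single share of 6.84% of that tissue would be needed to account for the reads. Of 118 members with 20 or more expected reads, 61.9% lay below what that share predicts and 28.8% lay above it, beyond their counting intervals, and with the infected or the control hepatopancreas as source, at the shares of 2.12% and 2.45% needed there, 80.4% of 97 and 79.0% of 100 members lay below. Relative to the survivor hepatopancreas, the 118 members' shares of reads in the survivor stomach had a median of 2.72% (quartiles 1.38% and 10.8%). The intervals allow for counting error only, and a wider spread was not tested. Carry-over of these 3 profiles, each at 1 share with counting error alone, is therefore argued against as the whole cause. Carry-over from a part of the hepatopancreas with another profile, or expression in the stomach itself, may still contribute.

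Several named genes were present in some pools and at 0 reads in others alike in both tissues, while their clusters' sums passed no rule. Of 59 genes at 0 in the control stomach, higher in the survivor stomach and with 20 or more reads in the survivor hepatopancreas, 37.3% (22 genes, exact interval 25.0% to 50.9%) were also at 0 in the control hepatopancreas, against 1.49% of genes of like abundance there, as alleles carried by a pool's shrimp would give; a response shared by the tissues would do so too. In 78 cases a gene was at 0 in both tissues of a pool and well measured in both tissues of another. In 30.8% of them (20.8% to 42.2%) a sister feature of the same cluster was at least 4 times higher where the gene was absent. The share was 6.82% (5.69% to 8.08%) among 1790 cases of a gene present in both pools. A case is a gene in an ordered pair of pools, so 1 gene can enter several times. The intervals treat cases as independent and may be too narrow. Reads split between alleles or near-identical copies may thus account for part of these calls. How general such splitting is stays open. Clusters were counted once in each of the 6 comparisons and summed. In this sum, 175 held both a higher and a lower call, against 339 to 389 in 1000 shuffles. Members often moved together (525 in the sum, against 320 to 376), which lowers that number whether or not reads are split. The bound set beforehand therefore decides nothing.

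The tissue difference gave 2925 calls in edgeR in the real split of the 6 libraries and 0 in the highest of the other splits, which reached at most 135 genes at an unadjusted p below 0.05, 511 calls in DESeq2 and 0 in limma. The real split was the 1 of 10 with as many calls, and 10 splits cannot give a share under 0.05. The other splits mix the tissues, so the tissue difference stays in their residual spread and lowers their calls by design. Their low numbers therefore say little about chance.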

How the results depend on the processing

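Counts summed over assembly clusters and the read minimum in the control were chosen after seeing the data, and the sum over isoforms of a gene was not run because the identifiers carry no isoform part; name-based gene lists were not run either. Of the alternative values of the main results, 106 lay within 1.5 times of a reported count or within the resampling interval of a reported median or correlation, and 50 did not; the cause was not tested. Without a minimum read number, the infected stomach had 567 lower genes, the survivor stomach had 1386 higher than control and 1371 higher than infected, and the infected hepatopancreas had 362 higher. Thinned, the infected stomach had 241 lower genes. Summed over clusters, lower calls numbered 234 in the infected and 299 in the survivor stomach, and higher calls 134 in the infected hepatopancreas. Scaled by library totals, the survivor hepatopancreas had 1077 genes higher than control and 1185 higher than infected.

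With at least 100 reads, rho between tissues was 0.51 for infection and 0.46 for survivors, r within the stomach 0.72, and genes called alike numbered 22, 35, 116 (stomach) and 54 (hepatopancreas). With an 8-fold rule they numbered 28, 77, 254 and 82. Thinned, r was 0.71 in the stomach and 0.39 in the hepatopancreas. With at least 20 reads in the control, genes called alike between tissues numbered 36 for infection and 45 for survivors, with a survivor rho of 0.45, and in the stomach 189 were called alike at r = 0.44, with r = 0.26 in the hepatopancreas; these leave out genes absent from the control.

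The stomach-enriched median for infected against control was 0.33 with 64-fold enrichment and -0.48 with 200 reads, so it has no stable sign. For survivors against control it was -0.12 and -0.19, and against infected -0.48 with 200 reads and -0.56 thinned. The hepatopancreas-enriched median for survivors against control was -1.62 with 4-fold enrichment, -1.15 by totals and -2.28 with 200 reads. Against infected it was -1.83 with 4-fold and -2.54 with 64-fold enrichment, -1.46 by totals and -2.44 with 200 reads.

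The tissue test without an expression filter called 3214 and 4434 genes. Leaving out 1 pool in turn gave 0 to 2743 genes higher in the hepatopancreas and 0 to 2739 in the stomach, the 0 coming without the control pool and without the infected pool. Without a block for pool it called 1420 and 1564. Of the named genes' alternative values in comparisons of pools, 115 stayed within their counting interval and 5 moved. On the authors' scaled matrix, TRINITY_DN13601_c0_g1 moved from -12.10 (infected) and -10.97 (survivor) to -7.95 in log2 ratio against the control stomach. In the survivor against the control hepatopancreas it moved from -11.40 to -7.95. TRINITY_DN13601_c0_g2 moved on that matrix from -10.81 to -7.81 in the survivor against the infected stomach. In each of these comparisons on that matrix, the gene had 0 reads in the library on the lower side. Its log2 ratio then depends on the value that stands in for 0 reads, which differs between the settings. These moves therefore do not measure a change in level. The floor of 3 reads was not applied to these log2 ratios. Thinned, TRINITY_DN13839_c1_g1 moved from 10.92 to 13.20 in the survivor against the infected stomach. A comparison of pools paired by tissue was not run, since the 2 tissues of a pool come from the same shrimp and are not replicates of it.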

Other observations

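These values were chosen after the data were seen. The infected stomach held 277 genes with at least 20 reads there and 0 in the other 5 libraries, against 6 to 27 in each of the others. They came from 196 assembly clusters and took 0.941% of that library's reads. Whether they are shrimp genes was not tested. Thinned to equal depth, 161 such genes were left in the infected stomach and 4 to 26 in the others.

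Genes with at least 20 reads in both tissues of a pool and 0 reads in both other pools numbered 3 in the control, 0 in the infected and 19 in the survivor pool. The 19 genes of the survivors came from 16 clusters and took 0.157% of the reads of their stomach and 0.146% of those of their hepatopancreas. TRINITY_DN21765_c0_g5 was one of them, at 263.4 CPM in the stomach and 198.4 in the hepatopancreas, in a cluster that held 607.3 to 1049 CPM in the 6 libraries.

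TRINITY_DN13796_c0_g3 had 0 reads in both control libraries, 71.0 CPM in the infected and 420.2 in the survivor stomach, and 121.9 and 362.7 in the corresponding hepatopancreas libraries. Its cluster of 3 features did not rise alongside, at 868.4, 554.9 and 674.1 CPM in the control, infected and survivor stomach and 992.0, 704.3 and 558.7 in the hepatopancreas, and another member, TRINITY_DN13796_c0_g2, singled out after its values were seen, ran the other way, at 868.4, 421.3 and 110.6 in the stomach and 992.0, 494.1 and 100.4 in the hepatopancreas. TRINITY_DN12136_c0_g1, the gene with the lead among those lower in the survivor than in the infected hepatopancreas, had 0 reads in each stomach library.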
